A study of Homo sapiens and Mus musculus with 154 samples.

How the data were processed

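The series examined cells treated with MYCi975, a small-molecule inhibitor of the transcription factor MYC, at 10 µM against 0.2% DMSO. The cells were 22Rv1, a human prostate cancer line, and MCF7, a human breast cancer line. Per the labels, all cells were harvested 72 h after plating, so that the treatment times were counted back from the harvest. Of 154 samples, 116 had a deposited file: 92 chromatin immunoprecipitation (ChIP) libraries, 12 libraries of accessible chromatin (ATAC) and 12 RNA libraries. The other 38 samples had none and were not analysed. They were 31 input libraries and 7 further ChIP libraries: 2 of WDR5, 3 of MYC with another antibody, 1 from the DU145 line, 1 from the mouse MycCaP line.

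The authors aligned the reads with Bowtie 1.2.2, Bowtie2 2.2.6 or STAR 2.7.5, per the labels. For the RNA, the deposited files give raw counts of fragments per gene from Subread 1.6.1 (featureCounts), with no normalization. For each ChIP library, the authors' peak lists came from HOMER 4.11.1. Per the file headers, peaks had a fold over input of at least 4, a Poisson p over input of 0.0001, a fold over the local region of at least 4 and, for the transcription factors, an FDR of 0.001. The deposited ChIP signal of a peak is its tag count scaled to 10000000 tags, the deposited ratio is its fold over the scaled input, and the deposited score is the peak caller's own. The H3K27ac peaks were stitched regions of variable length. Per the file headers, all 3 AR libraries of a condition, and likewise all 3 FOXA1 libraries in 22Rv1, were called against 1 input library; the CTCF libraries labelled 24 h were called against a 48 h input, and the treated MCF7 FOXA1 libraries against a DMSO input. For ATAC, the authors' peaks came from MACS2 2.2.6 with a shift of -75, an extension of 150 and a p of 0.01. Their deposited signal is the pileup at the summit, their ratio is the fold enrichment over the genome-wide background, and their p-values are given as -log10 p.

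The authors also deposited 8 tables of differential sites at 48 h from DiffBind 3.12. These deposited tables give log2 concentrations per condition, a log2 fold, a p-value and an FDR per site. A further deposited table, of MYC-bound genes, gives RNA signal per library, which is the gene counts divided by a single factor per library, with log2 folds and adjusted p-values. The test engine and the normalization behind the 8 tables are not stated, so their counts of sites are reported as the authors' own. No column of per-sample values lacked a sample (0 columns). The coordinates are of the human genome build hg38.

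RNA was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10) on all 12 libraries, with the group as the only term. Benjamini-Hochberg adjusted p under 0.05 counted as changed. Standard errors of log2 fold changes are the fold divided by the root of the F statistic. CPM values (counts scaled to library size) are TMM scaled, and log2 CPM used a prior count of 2. TMM takes most genes as unchanged, so higher and lower RNA are relative to the other genes. A change in total RNA per cell could not be measured. Before the data were examined, 29 lists with 746 entries were written, and 27 of them had at least 2 tested genes. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, against all other tested genes, and with an estimated correlation and fry beside it. A promoter was counted as MYC-bound when a DMSO consensus site lay within 1 kb of a gene start.

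For MYC and MAX, peaks per library, the share of tags in peaks and the share of consensus sites kept were compared with DMSO by exact two-sided permutation tests. Each test had 4 against 4 libraries and 70 splits, so 0.0286 was the smallest possible p, and p-values were adjusted over the 10 comparisons of each measure. A consensus site was called in at least 3 of the 4 DMSO libraries. For a DMSO library, the consensus came from the other 3 (called in at least 2), so its share was not counted against itself. DMSO and treated libraries were therefore scored on different sets of sites, with the looser rule for DMSO. Groups of 3 allow no p under 0.1. Groups of 2 allow none under 0.333 and were not tested. Overlaps between the deposited tables used Fisher's exact test over sites. Sites are not independent replicates, so only shares and odds ratios are given.

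The rule for named genes was also fixed before the data were examined. It names 9 genes of the chromatin factors and partners in the labels, and the 10 largest rises and falls per contrast (5 for 48 h against 24 h). These had to be protein-coding, at a mean log2 CPM of at least 3, with every treated library beyond every control library. It also names up to 3 members of each list with the smallest p, at a mean log2 CPM of at least 1. Of each deposited table it names the 3 largest falls and rises among sites within 1 kb of a gene start with FDR under 0.05 and a concentration above the table's median, plus the promoter sites of 19 genes. Only a part of the promoter sites of these genes is given below. Of the largest falls and rises, 1 was left out because it lies on the Y chromosome.

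The RNA libraries held 3933185 to 9896208 counts in genes, the ChIP libraries 8396116 to 27342085 tags and the ATAC libraries 35388879 to 72314696 tags. On simulated data at the depths of the 48 h and DMSO libraries, the RNA test recovered 40 of 50 genes raised 1.5-fold and 33 of 50 lowered 1.5-fold. At 2-fold it recovered 46 and 41 of 50, and it called 6 of 14206 genes that had not been altered. Few genes were altered there, so scaling when most genes change was not tested.

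Alternatives covered the tool (DESeq2 1.42.0), its size factors, no filter on low counts, the 2 compared groups alone, the replicate number as a term, the deposit set (replicates 1 and 2 or 3 and 4), each library left out in turn, stricter peaks (fold of at least 8), another consensus or overlap, equal numbers of peaks, an FDR of 0.01, a 2-fold minimum and centred folds. Scaling by spike-in features was planned, but the count files hold none. Counts of motifs at changed sites were planned, but no genome sequence was used here, so they were not run. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.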

Results

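The series asked how MYCi975 changes transcription factor binding and the epigenome over time. MYC and its dimer partner MAX were profiled by ChIP in 22Rv1 cells, with 4 libraries each in DMSO and after 1, 4, 8, 24 and 48 h. H3K27ac, a histone mark of active promoters and enhancers, had 2 libraries at each of these times. The androgen receptor (AR) and FOXA1, a factor that opens chromatin for AR, had 3 libraries each in DMSO and at 48 h. CTCF, which organises chromatin loops, had 2 in DMSO and 2 at 24 h. MGA, MNT and MXD1, other partners of MAX, had 2 each in DMSO and at 48 h. FOXA1 in MCF7 had 2 per condition, and ATAC had 3 per condition in each line, at 48 h. RNA of 22Rv1 had 4 libraries each in DMSO, at 24 h and at 48 h.

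The RNA libraries held between 3933185 (48 h, replicate 3) and 9896208 (DMSO, replicate 2) counts in genes. The 3 shallowest libraries were all treated; the other 2 were 24 h replicate 2 with 4699547 and 48 h replicate 4 with 5390339 counts. Mitochondrially encoded transcripts took 10.09%, 10.64% and 7.83% of the counts of 24 h replicate 2, 48 h replicate 3 and 48 h replicate 4, against 4.01% to 6.50% in the other 9 libraries. The counts of changed genes, of lists changed against DMSO and the gap at MYC-bound genes are also given without these 3 libraries. The MYC and MAX libraries held 8396116 to 17077336 tags.

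After 24 h of MYCi975, RNA of genes for DNA replication fell and RNA of amino acid stress genes rose in 22Rv1. Of 14686 genes tested, 4830 were higher and 4726 lower than in DMSO; 1212 rose and 635 fell by at least 2-fold. The steepest falls were genes that act in S phase. UHRF1, which maintains DNA methylation at replication forks, fell from 70.3 ± 5.37 CPM (SD, n = 4) to 8.77 ± 3.63 (log2 fold change -3.04 ± 0.13 SE, adjusted p = 3.64e-17). CLSPN, a checkpoint adaptor, changed by -2.94 on the log2 scale, the thymidine kinase TK1 by -2.77, the ribonucleotide reductase subunit RRM2 by -2.65 and the cyclin CCNE2 by -2.63. The replication factors MCM10 (-2.49), GINS2 (-2.45) and MCM4 (-2.44) and the histones H2AC4 (-2.57) and H2BC3 (-2.55) completed the 10 largest falls. The largest rise was LAMP3, a lysosomal membrane protein, from 0.275 ± 0.191 to 59.0 ± 6.30 CPM (n = 4; log2 fold change 7.65 ± 0.18 SE, adjusted p = 7.07e-23). GDF15, a secreted stress cytokine, rose from 14.79 ± 1.295 to 321 ± 39.8 CPM (4.44 on the log2 scale). PLEKHH2 (5.35), DMGDH (5.33), CALCA (5.27), STK32A (4.85), NIBAN1 (4.37), RELN (4.35), LARP6 (4.31) and CAPN5 (4.08) also rose. The groups did not overlap for 8387 of the tested genes (57.1%), against 2.86% by chance. Leaving out the 3 shallow libraries gave 9817 changed genes in place of 9556.

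All 42 members of the list for DNA replication and S phase fell at 24 h, with a median log2 fold change of -1.82 (camera adjusted p = 1.44e-23, and adjusted p = 0.0112 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, changed by -2.29. All 31 tested replication-dependent histone genes fell (median -1.48, adjusted p = 3.23e-16), among them H1-5 (-2.08) and H3C3 (-1.85). Their call was lost at adjusted p = 0.0974 with an estimated correlation. Reads shared between near-identical copies of these genes were not measured. In the list for nucleotide and one-carbon synthesis, 23 of 28 fell and 4 rose (median -0.75, adjusted p = 1.90e-06, and adjusted p = 0.0274 with an estimated correlation). DHFR, which makes tetrahydrofolate, changed by -2.05. Of 40 mitosis genes, 25 fell, 3 rose and 12 did not pass (median -0.32, adjusted p = 0.000225, but adjusted p = 0.235 with an estimated correlation). The proliferation marker MKI67 changed by -1.04, BIRC5 by -0.96 and ANLN by -0.84.

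Genes that MYC is known to activate were lower. Of 57 canonical MYC-activated genes, 47 fell and 2 rose at 24 h (median -0.59, adjusted p = 2.18e-11, and adjusted p = 0.0168 with an estimated correlation). The members with the smallest p also act in DNA replication and repair: MCM4 (-2.44), MCM5 (-1.98) and UNG (-1.81). Of 59 ribosome biogenesis genes, 52 fell and 3 rose (median -0.59, adjusted p = 1.55e-11, and adjusted p = 0.0112 with an estimated correlation). PA2G4 fell from 661 to 322 CPM (-1.04), NOP56 changed by -0.98 and NOP16 by -1.12. Cytosolic ribosomal protein genes moved the other way. Of 75 tested, 70 were higher and 1 lower (median 0.39, adjusted p = 5.03e-13), among them RPL12 (0.60), RPL15 (0.64) and RPL13A (0.64). That call was lost at adjusted p = 0.256 with an estimated correlation. Reads shared with processed copies of these genes were not measured. Of 25 cholesterol synthesis genes, 22 fell and 1 rose (median -0.65, adjusted p = 5.40e-08, and adjusted p = 0.0112 with an estimated correlation), with DHCR24 (-1.94), EBP (-1.31) and ACAT2 (-1.16). Of 12 heat shock genes, 11 fell (median -0.47, adjusted p = 2.11e-05, and adjusted p = 0.0246 with an estimated correlation). The chaperones HSPH1 (-1.40), DNAJA1 (-1.18) and HSP90AA1 (-1.03) led them.

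All 26 genes of the ATF4 and amino acid stress response rose at 24 h (median 1.67, adjusted p = 3.23e-16, and adjusted p = 0.0228 with an estimated correlation). DDIT3, a stress-induced transcription factor, rose from 32.6 to 343 CPM (3.40), and DDIT4, an inhibitor of mTORC1, from 16.1 to 108 CPM (2.76). Of 19 cytosolic tRNA synthetases, 12 rose and 6 fell (median 0.43, adjusted p = 0.0465, but adjusted p = 0.463 with an estimated correlation), with SARS1 (1.40), AARS1 (1.46) and YARS1 (0.84). Of 25 p53 targets, 15 rose and 4 fell (median 0.47, adjusted p = 0.00653, but adjusted p = 0.0737 with an estimated correlation). The death receptor TNFRSF10B (1.88), the cell cycle inhibitor CDKN1A (1.41) and the apoptosis gene BBC3 (1.58) were among the rises. Of 14 immediate early and AP-1 genes, 9 rose and 3 fell (median 0.96, adjusted p = 0.00997, but adjusted p = 0.418 with an estimated correlation), with KLF4 (2.53), JUND (1.47) and DUSP1 (1.47).

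Of 26 androgen receptor targets, 18 fell and 5 rose at 24 h (median -0.41, adjusted p = 0.00997, but adjusted p = 0.235 with an estimated correlation). NKX3-1, a prostate homeobox gene, fell from 391.6 to 132 CPM (-1.58), and SLC45A3 changed by -1.72. Of 15 interferon and antigen presentation genes, 11 rose and 3 fell (median 0.37, adjusted p = 0.0465, but adjusted p = 0.113 with an estimated correlation), with MX1 (1.02) and B2M (0.66) higher and OAS3 (-2.33) lower. Of 6 basal and mesenchymal markers, 5 rose and 1 fell (median 0.67, adjusted p = 0.0465, but adjusted p = 0.267 with an estimated correlation). CD44 (0.91) and FN1 (1.09) were higher and CDH2 (-0.98) lower. Leaving out any of 5 single libraries (DMSO replicates 3 and 4, or any 24 h replicate but the second) ended 1 or more of the tRNA synthetase, interferon and basal calls, with adjusted p from 0.0505 to 0.0621. Leaving out the 3 shallow libraries ended all 3 calls (0.0522 to 0.0646), and the replicate number as a replicate block ended the tRNA synthetase (0.0511) and interferon (0.0512) calls. With no filter on low counts the basal call was lost as well (median 0.48, camera adjusted p = 0.0843).

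The other lists did not pass at 24 h. For lysosome and autophagy genes, 12 of 23 rose and 5 fell (adjusted p = 0.0624, but 0.0345 without DMSO replicate 2 and 0.0449 without 24 h replicate 2), with SQSTM1 (1.66), MAP1LC3B (1.66) and GABARAPL1 (2.39) higher. For endoplasmic reticulum chaperones, 8 of 19 rose and 10 fell (adjusted p = 0.357). The stress sensor ERN1 (2.86) was higher and PDIA4 (-1.43) and CRELD2 (-1.69) lower. For NRF2 genes, 6 of 17 rose and 6 fell (adjusted p = 0.753), with the cystine transporter SLC7A11 (1.65) and the ferritins FTL (1.18) and FTH1 (1.24) higher. For glycolysis and hypoxia genes, 8 of 24 rose and 11 fell (adjusted p = 0.448), with NDRG1 (0.97) higher and PKM (-0.89) lower. This list's median (-0.17) and test pointed down and its mean (0.05) up. Neuroendocrine markers had 3 of 9 higher and 5 lower (adjusted p = 0.753), with a median of -0.14 and a mean of 0.08. CHGB (0.79) was higher and SYP (-0.39) lower. Prostate luminal genes had 2 of 13 higher and 5 lower (adjusted p = 0.430), with FOLH1 (0.84) higher and SPDEF (-0.42) lower. MYC network genes had 6 of 13 higher and 4 lower (adjusted p = 0.5259), with MYCL (2.88) and MXI1 (0.85) higher. Genes of chromatin architecture and WDR5 complexes had 6 of 20 higher and 9 lower (adjusted p = 0.312), with SMC1A (-1.14) lower and KMT2C (0.54) and STAG2 (0.69) higher. Mitochondrially encoded transcripts had 6 of 13 higher and 3 lower (adjusted p = 0.504), with ND4 (0.58) and CYTB (0.41) higher and ND6 (-0.60) lower.

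Markers of other cell types were few in 22Rv1. Breast luminal markers had 1 of 5 tested higher and 4 lower (adjusted p = 0.357), with XBP1 (0.69) higher and GATA3 (-0.46) and AGR2 (-0.51) lower. Fibroblast markers had 4 of 5 tested higher (adjusted p = 0.312), with COL1A1 going from 6.59 to 19.5 CPM, ACTA2 from 3.38 to 6.83 and COL1A2 from 1.22 to 5.74 ± 5.11 (SD, n = 4). The COL1A2 call was lost with DESeq2 (adjusted p = 0.0986). Of the leukocyte markers, CD68 alone was tested and rose (2.15), and of the endothelial markers 0 were tested. Adjusted over the list alone, the counts at 24 h differed in 4 lists. The lists for cholesterol synthesis, for nucleotide and one-carbon synthesis and for glycolysis then had 23, 24 and 12 lower members, and the p53 list had 16 higher ones. With the preset correlation 16 of 27 lists passed at 24 h, and with an estimated one 7 did. Without the 3 shallow libraries, 13 passed.

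**Figure D1:**
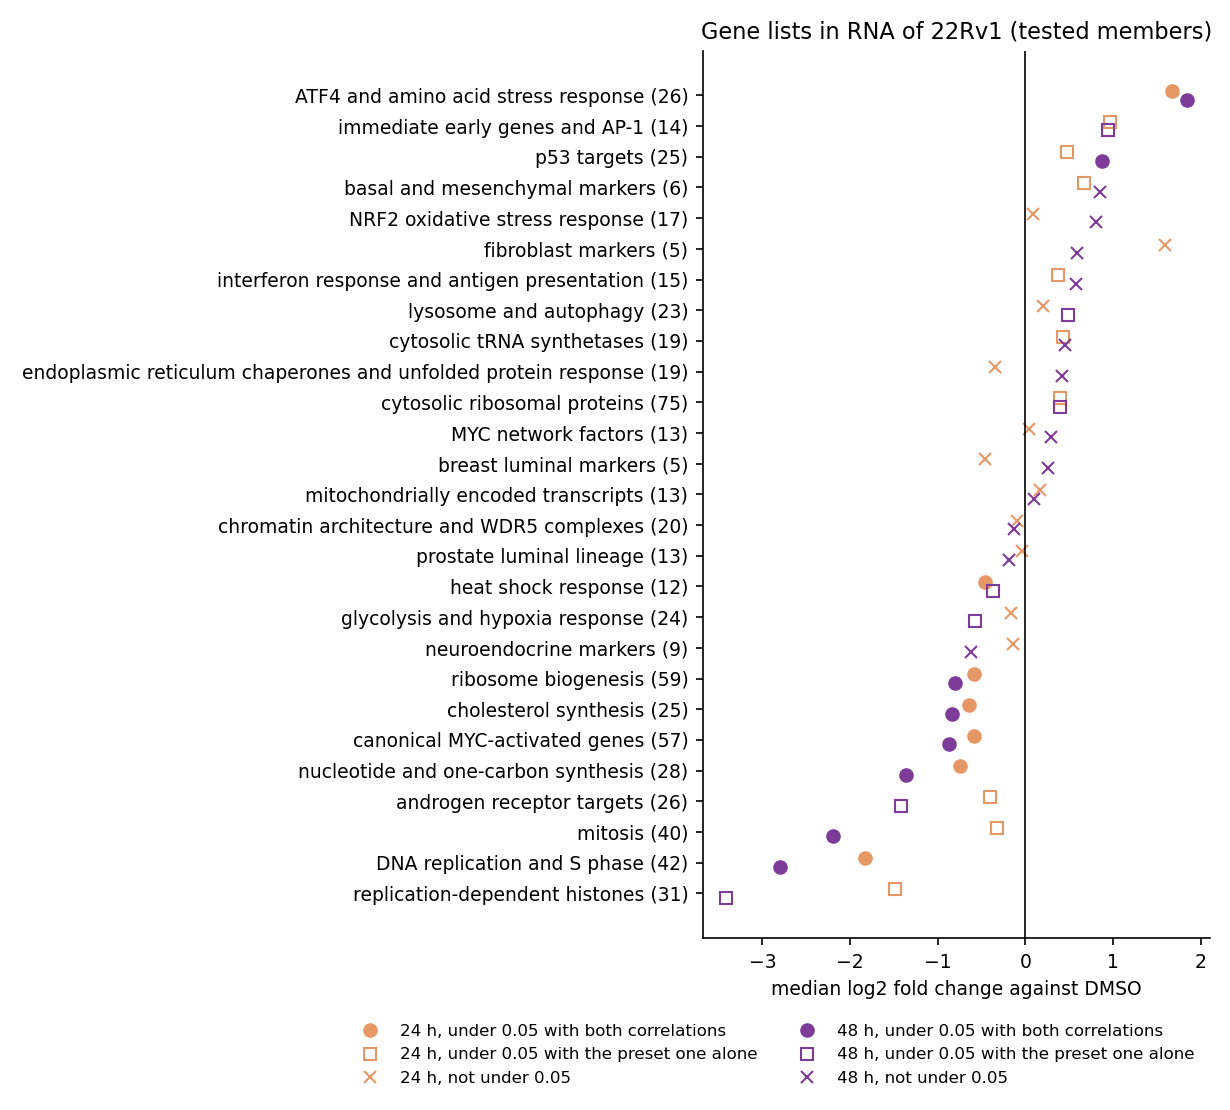
Median log2 fold change against DMSO of the tested members of 27 gene lists (their number in brackets) at 24 h and 48 h, 4 libraries per group. Filled circles passed camera with both correlations, open squares with the preset one alone, and crosses with neither; the list for DNA replication and S phase went from -1.82 to -2.80 and that for mitosis from -0.32 to -2.19.

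At 48 h more genes had changed and the falls in cell cycle genes were deeper. Of the 14686 genes, 5541 were higher and 5466 lower than in DMSO, and 1889 rose and 1964 fell by at least 2-fold. With 74.9% of genes called changed and a median log2 fold change of 0.009, the balance of rises and falls depends on the scaling. Directions are relative to the other genes. UHRF1 reached 1.04 ± 0.248 CPM (SD, n = 4; log2 fold change -6.10 ± 0.21 SE, adjusted p = 4.33e-20). RRM2 (-5.08), CLSPN (-4.95), GINS2 (-4.56), TK1 (-4.54) and the histones H2BC3 (-5.32), H2AC4 (-4.87), H2BC6 (-4.71), H1-5 (-4.58) and H2BC18 (-4.57) were the other large falls. LAMP3 reached 111 ± 5.35 CPM (n = 4; 8.54 ± 0.16 SE, adjusted p = 9.03e-26). PLEKHH2 (6.77), DMGDH (6.12), STK32A (6.07), RELN (6.06), CALCA (6.04), CAPN5 (5.44), NIBAN1 (5.41), LARP6 (5.30) and GPNMB (5.39), a melanosome and lysosome protein, were the other large rises. The groups did not overlap for 9829 genes (66.9%), against 2.86% by chance. Without the 3 shallow libraries 10808 genes were called changed, in place of 11007.

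All 40 mitosis genes were lower at 48 h (median -2.19, adjusted p = 4.25e-19, and adjusted p = 0.0159 with an estimated correlation), with MKI67 (-3.08), ANLN (-2.53) and BIRC5 (-2.93). All 42 genes for DNA replication and S phase were lower (median -2.80, adjusted p = 3.01e-20, and adjusted p = 0.0159 with an estimated correlation), with MCM4 (-4.03), PCNA (-3.58) and MCM10 (-4.46). The 31 histone genes were lower (median -3.41, adjusted p = 1.94e-16, but adjusted p = 0.0899 with an estimated correlation), with H3C3 (-4.11) and H3C2 (-4.30). For nucleotide and one-carbon synthesis, 23 of 28 fell and 4 rose (median -1.36, adjusted p = 1.88e-06, and adjusted p = 0.0274 with an estimated correlation), with DHFR (-3.81) and the thymidylate synthase TYMS (-2.56). Of the canonical MYC-activated genes 49 of 57 fell and 3 rose (median -0.87, adjusted p = 9.68e-11, and adjusted p = 0.0159 with an estimated correlation), with MCM5 (-3.21) and UNG (-2.41). Of the ribosome biogenesis genes 52 of 59 fell and 2 rose (median -0.81, adjusted p = 1.68e-10, and adjusted p = 0.0159 with an estimated correlation). The nucleolar proteins NCL (-1.36) and TCOF1 (-1.62) and PA2G4 (-1.34) were among them. Of the cholesterol genes 21 of 25 fell and 1 rose (median -0.83, adjusted p = 3.90e-06, and adjusted p = 0.0159 with an estimated correlation), with DHCR24 (-2.66), ACAT2 (-1.60).

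The ATF4 list had 24 of 26 members higher and 1 lower at 48 h (median 1.84, adjusted p = 9.68e-11, and adjusted p = 0.0472 with an estimated correlation), with GDF15 (5.26), DDIT3 (4.14) and ATF3 (3.94). Of the p53 targets 20 of 25 rose and 3 fell (median 0.87, adjusted p = 6.38e-05, and adjusted p = 0.0164 with an estimated correlation). CDKN1A reached 341 CPM from 49.8 (2.78), TNFRSF10B rose by 2.50 and GADD45A by 2.75 on the log2 scale. Of the androgen receptor targets 19 of 26 fell and 4 rose (median -1.42, adjusted p = 0.000217, but adjusted p = 0.0899 with an estimated correlation). NKX3-1 reached 48.3 CPM (-3.02) and the kallikrein KLK4 changed by -2.56. Cytosolic ribosomal protein genes had 67 of 75 higher and 2 lower (median 0.39, adjusted p = 7.17e-09, but adjusted p = 0.350 with an estimated correlation), with RPL12 (0.80), RPL37 (0.93) and RPL4 (0.68). Lysosome and autophagy genes had 15 of 23 higher and 5 lower (median 0.49, adjusted p = 0.0191, but adjusted p = 0.350 with an estimated correlation), with SQSTM1 (2.45), MAP1LC3B (2.28) and GABARAPL1 (3.46). Glycolysis and hypoxia genes had 4 of 24 higher and 15 lower (median -0.58, adjusted p = 0.0281, but adjusted p = 0.350 with an estimated correlation). PKM (-1.68) and LDHA (-1.61), enzymes of the last steps of glycolysis, were lower, while VEGFA, an angiogenic factor, was higher (3.42). Immediate early genes had 9 of 14 higher and 2 lower (median 0.94, adjusted p = 0.0203, but adjusted p = 0.393 with an estimated correlation), with KLF4 (3.25) and JUND (1.86). Heat shock genes had 1 of 12 higher and 9 lower (median -0.37, adjusted p = 0.0187, but adjusted p = 0.139 with an estimated correlation), with HSPE1 (-1.71), DNAJA1 (-1.15) and HSPH1 (-1.10).

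Lists that did not pass at 48 h included NRF2 genes, with 11 of 17 higher and 5 lower (adjusted p = 0.0986). Its members FTH1 (2.62), FTL (1.49) and SLC7A11 (1.84) were higher. Endoplasmic reticulum chaperones had 11 of 19 higher and 8 lower (adjusted p = 0.508), with ERN1 (3.97) and ATF6 (1.68) higher and CRELD2 (-1.80) lower. The tRNA synthetases had 12 of 19 higher and 7 lower (adjusted p = 0.0922), with SARS1 (1.64), AARS1 (1.72) and WARS1 (1.39) higher. Interferon genes had 10 of 15 higher and 3 lower (adjusted p = 0.0641), with IRF1 (1.86) and STAT1 (0.58) higher and OAS3 (-4.35) lower. Basal markers had 4 of 6 higher and 1 lower (adjusted p = 0.112), with CD44 (0.93) and ITGA6 (1.71) higher and CDH2 (-1.29) lower. Neuroendocrine markers had 1 of 9 higher and 6 lower (adjusted p = 0.107), with SRRM4 (-1.10), SYP (-1.11) and SCG3 (-1.02) lower. Prostate luminal genes had 3 of 13 higher and 8 lower (adjusted p = 0.138), with SPDEF (-1.56) and HOXB13 (-1.09) lower. MYC network genes had 8 of 13 higher and 4 lower (adjusted p = 0.448), with MYCL (2.57) higher and MXD3 (-2.20) lower. Chromatin architecture genes had 9 of 20 higher and 9 lower (adjusted p = 0.807), with SMC1A (-1.71) lower and KMT2C (1.05) and CREBBP (1.02) higher. Mitochondrially encoded transcripts had 5 of 13 higher and 2 lower (adjusted p = 0.807), with ND4 (0.61) higher and COX3 (-0.56) and ND6 (-0.88) lower; their share of counts was highest in the shallow libraries.

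For breast luminal markers at 48 h, 3 of 5 were higher and 2 lower, with XBP1 (1.16) higher and GATA3 (-0.94) and GREB1 (-2.53) lower. The median (0.26) and the test (adjusted p = 0.807) pointed up and the mean (-0.33) down. The same held for fibroblast markers (median 0.58, mean -0.22, adjusted p = 0.807), with 2 of 5 higher, COL1A1 at 17.6 and ACTA2 at 5.98 CPM, and 1 lower. CD68 reached 21.0 CPM (3.13). Adjusted over the list alone, the counts at 48 h differed in the MYC network list (9 higher) and the androgen receptor list (5 higher). With the preset correlation 15 of 27 lists passed at 48 h, and with an estimated one 8 did. Without the 3 shallow libraries 15 passed. With no filter on low counts 20 of 29 passed, among them NRF2 (adjusted p = 0.0191), tRNA synthetases (0.0371), interferon (0.0348), neuroendocrine (0.0348) and prostate luminal genes (0.0371). The interferon list also passed without DMSO replicate 2 (adjusted p = 0.0493) or 48 h replicate 1 (0.0488).

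A direct comparison of 48 h with 24 h asked what changed on the second day. It gave 3561 genes higher and 3676 lower; 262 rose and 802 fell by at least 2-fold. The metallothionein MT1G rose from 32.6 ± 6.86 to 134 ± 15.2 CPM (n = 4; 2.01 ± 0.09 SE, adjusted p = 2.13e-16), and GPNMB (1.92), MGLL (1.79), PTPN21 (1.72) and RELN (1.71) also rose. DHRS2, a dehydrogenase, fell from 66.2 ± 9.31 to 5.87 ± 0.999 CPM (n = 4; -3.45 ± 0.12 SE, adjusted p = 8.47e-19), and UHRF1 (-3.06), H2BC3 (-2.77), H2BC6 (-2.73) and H3C2 (-2.65) also fell. All 40 mitosis genes were lower at 48 h than at 24 h (median -1.87, adjusted p = 2.03e-34, and adjusted p = 0.00726 with an estimated correlation). Androgen receptor targets had 20 of 26 lower (median -0.68, adjusted p = 1.93e-07, and adjusted p = 0.0347 with an estimated correlation). The p53 targets had 17 of 25 higher and 0 lower (median 0.46, adjusted p = 1.99e-06, and adjusted p = 0.0112 with an estimated correlation). Endoplasmic reticulum chaperones had 14 of 19 higher (median 0.39, adjusted p = 9.03e-06, and adjusted p = 0.0414 with an estimated correlation). The 42 genes for DNA replication and S phase had 40 lower (median -1.12, adjusted p = 6.09e-22, and adjusted p = 0.0105 with an estimated correlation), and all 31 histone genes were lower (median -1.87, adjusted p = 3.30e-22, and adjusted p = 0.0414 with an estimated correlation). NRF2 genes had 11 of 17 higher and 4 lower (median 0.31, adjusted p = 0.0163, but adjusted p = 0.0676 with an estimated correlation). For cytosolic ribosomal proteins, 56 of 75 did not pass (median 0.00, adjusted p = 0.746). Without the shallow libraries 6686 genes were called changed, in place of 7237.

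RNA of MYC itself fell, from 352 ± 14.7 CPM (SD, n = 4) in DMSO to 224 ± 14.3 at 24 h (log2 fold change -0.65 ± 0.06 SE, adjusted p = 1.17e-10) and 90.7 ± 8.69 at 48 h (-1.95 ± 0.06 SE, adjusted p = 8.26e-21). MXD1, a MAX partner that opposes MYC, rose by 0.49 at 24 h (adjusted p = 4.90e-05) and 1.01 at 48 h (adjusted p = 8.78e-11). MAX changed by -0.14 at 24 h (adjusted p = 0.131) and by 0.24 at 48 h (adjusted p = 0.00708). Without the shallow libraries its 48 h value was 0.15 (adjusted p = 0.110), and in replicates 1 and 2 alone 0.13 (adjusted p = 0.266). MNT changed by 0.23 and 0.29, and its 24 h call was lost with DESeq2 (adjusted p = 0.0566), without DMSO replicate 4 (0.0550), without 24 h replicate 3 (0.0548) and in replicates 1 and 2 alone (0.428). MGA changed by -0.20 and -0.27, with its 24 h call lost in replicates 3 and 4 alone (adjusted p = 0.0837). WDR5, a MYC cofactor, fell (-0.51 and -0.55), as did CTCF (-0.38 and -0.56). RNA of AR was at 666 ± 27.5 CPM in DMSO, 648 ± 31.0 at 24 h (adjusted p = 0.536) and 493 ± 25.6 at 48 h (-0.43, adjusted p = 3.03e-08). FOXA1 RNA was at 430 ± 7.72, 422 ± 9.35 (adjusted p = 0.608) and 366 ± 8.21 CPM (-0.23, adjusted p = 3.68e-05).

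**Figure D2:**
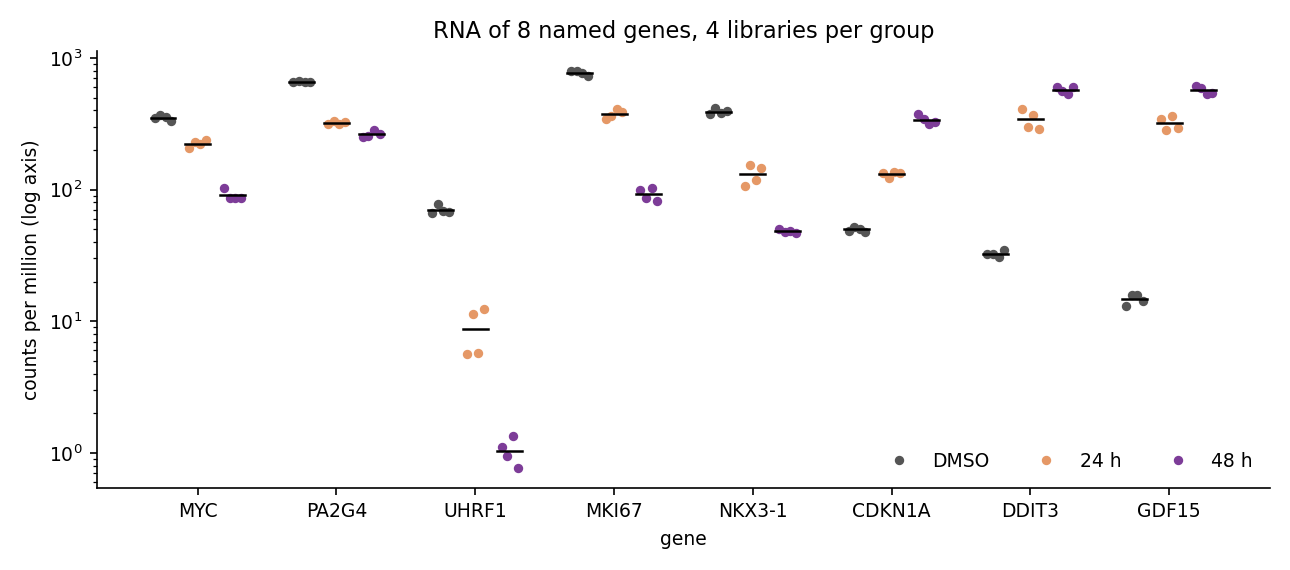
CPM (log axis) of 8 named genes in each of the 4 DMSO, 24 h and 48 h RNA libraries of 22Rv1; bars are means. MYC, PA2G4, UHRF1, MKI67 and NKX3-1 were lower and CDKN1A, DDIT3 and GDF15 higher at both times; MKI67 went from 774 through 377 to 92.3.

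Genes with MYC at their promoter in DMSO were compared with all others. Of the tested genes, 11434 had a DMSO consensus MYC site within 1 kb of their start and 3252 did not. At 24 h the median log2 fold change was -0.02 at bound and 0.18 at other genes, a difference of -0.20 with a camera p of 0.00958. Of the bound genes 4082 were lower and 3664 higher, against 644 and 1166 of the others. At 48 h the difference was -0.20 as well, with a camera p of 0.0943 at the preset correlation and p = 0.0225 with an estimated correlation. Each of the 4 treated libraries showed it at either time, with differences of -0.16 to -0.21. It was also negative in each of 10 bins of mean expression, with a mean of -0.12 at 24 h and -0.16 at 48 h. Without the 3 shallow libraries the difference was -0.18 at 24 h (with a camera p of 0.0164) and -0.16 at 48 h (0.129).

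The MYC and MAX time course asked when binding was lost. At 48 h MYC peaks per library were at 16510 ± 2046 (SD, n = 4), against 32491 ± 1246 in DMSO, a change of -49.2%. All 4 libraries at 48 h were below all 4 DMSO libraries (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.114). The share of tags in MYC peaks was 3.67% ± 1.1997 at 48 h and 8.68% ± 0.769 in DMSO (n = 4, exact p = 0.0286, adjusted p = 0.143). Of the 27506 MYC consensus sites, 49.8% lay within 1 kb of a gene start. On average 50.9% ± 4.97 of the 27506 had a peak at 48 h. The DMSO libraries, each scored on the sites of the other 3, had a peak at 83.9% ± 1.81 (n = 4, exact p = 0.0286, adjusted p = 0.143). Those sets followed a looser rule and held 30587 to 31347 sites, so the 2 shares are not of the same sites. At 4, 8 and 24 h, MYC peaks were at 27496 ± 2819, 26172 ± 4087 and 27053 ± 2933, with 3 of 4 libraries below all DMSO libraries (exact p = 0.0571 each, adjusted p = 0.114). At 1 h they were at 33577 ± 3433 (exact p = 0.600).

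MAX peaks were at 27276 ± 3901 at 48 h and 35321 ± 4276 in DMSO, a change of -22.8% (n = 4, exact p = 0.0571, adjusted p = 0.114). At 1, 4, 8 and 24 h their means were 35290, 34164, 32942 and 32091, with exact p from 0.314 to 1.0. These tests did not pair libraries by replicate number, so they can miss a shift within numbers. At 8 h MAX replicates 1 to 4 had 38128, 34308, 28587 and 30747 peaks. Each was below the DMSO replicate of its number (41060, 35947, 31342 and 32934). The same held for MAX at 48 h and for MYC at 4, 8 and 48 h. It did not hold for either factor at 1 or 24 h, or for MAX at 4 h. These are descriptions, and no p-value is given for them. The share of tags in MAX peaks was 5.68% ± 1.14 at 48 h and 8.70% ± 1.07 in DMSO (n = 4, exact p = 0.0286, adjusted p = 0.143). At 48 h 71.3% ± 6.34 of the MAX consensus sites had a peak. In DMSO it was 83.6% ± 5.68 of the more numerous sites on which those libraries were scored (exact p = 0.0571, adjusted p = 0.143). No comparison of the 10 in any of these 3 measures passed after adjustment. With 0.0286 as the smallest exact p, a change at 48 h alone could not pass this adjustment, whatever its size. The adjusted values therefore do not weigh against a loss at 48 h. The change in peaks at 48 h differed by -26.4 points between MYC and MAX (permutation of treatment labels within each factor, p = 0.237, adjusted p = 0.694). That permutation assumes no change in either factor, so whether the 2 changes differ stays open. With the same number of top peaks in every library, the share of consensus sites kept passed the adjusted threshold in 6 of the 10 comparisons, and the MYC differences from DMSO at 4 h (2.13 points, adjusted p = 0.0476) and 8 h (0.81 points, adjusted p = 0.444) turned upward. Here too DMSO and treated libraries were scored on different sets of sites.

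**Figure D3:**
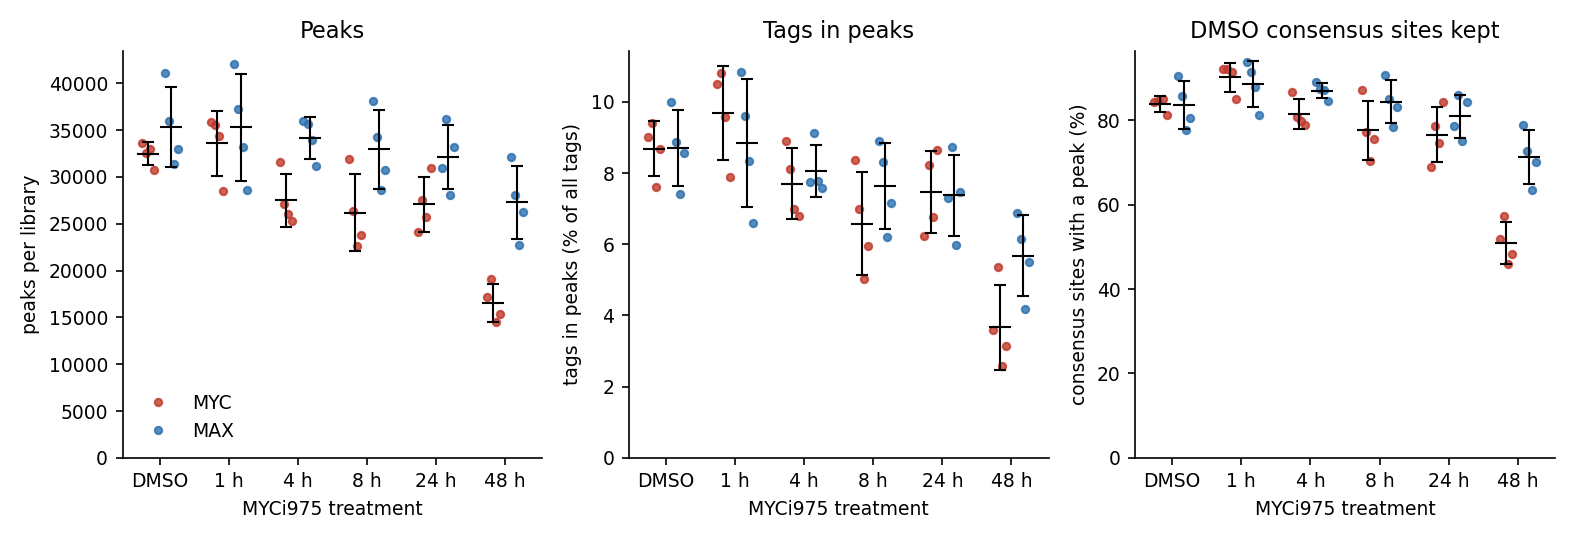
Peaks per library, tags in peaks (% of all tags) and DMSO consensus sites with a peak (%) for MYC and MAX in 22Rv1 by treatment time; points are the 4 libraries of a group, bars the mean and SD. At 48 h MYC peaks averaged 16510, against 32491 in DMSO.

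In the authors' tables, 34904 of 48023 MYC sites were lower at 48 h and 964 higher (FDR under 0.05), with a median log2 fold of -1.36 over the table. For MAX, 23023 of 56072 were lower and 1926 higher (median -0.66). Lower sites made up 97.3% of the changed MYC sites and 92.3% of the changed MAX sites. After each fold was centred on its table's median, these shares were 61.8% and 78.3%. The promoter site of CAD, a pyrimidine synthesis gene (chromosome 2, 27217327 to 27217609), had a MYC fold of -1.74 (FDR = 1.40e-15) and an overlapping MAX fold of -1.13 (FDR = 1.63e-06). The promoter sites of CDK4 (MYC -1.31, MAX -0.71), ODC1 (MYC -1.37 and -1.05, MAX -0.82 and -0.41) and NCL (MYC -1.73 and -1.11, MAX -0.71 and -0.62) were lower for both. At the MYC gene, sites at 127735965 to 127736381 and 127735492 to 127735882 of chromosome 8 had MYC folds of -1.86 and -1.09. Its MAX folds were -0.55 (FDR = 0.0568) and -0.35 (FDR = 0.184). MYC was also lower at promoter sites of MAX (-1.05), MXD1 (-0.92), MGA (-0.91), NPM1 (-0.84), FKBP5 (-1.70) and NKX3-1 (-2.05 and -1.18). With folds centred on the median of -1.36, the MYC folds at CDK4, MAX, MXD1, MGA and NPM1 turn positive, as does 1 of 2 at ODC1, NCL, NKX3-1 and MYC. For MAX (median -0.66) 1 of 2 turns positive at ODC1 and NCL, and both at MYC. The largest promoter falls by the rule were at LOC105375546 (-4.35), ACTL8 (-4.31) and TICRR (-4.31), a replication initiator gene, for MYC. For MAX they were at ACTL8 (-3.87), LOC105376381 (-3.30) and PGC (-3.29). Of the rises, MYC at KLHDC7B (chromosome 22, 50545596 to 50545943) went from a log2 concentration of 0.27 to 4.56, and at LOC105379311 from -0.14 to 4.47. At HIGD1AP9 it went from -0.40, the table's lowest DMSO value, to 5.00. MAX rose at DUX4L26 (2.74), RPA3 (2.51) and MOCOS (2.06).

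In the AR ChIP, peaks fell from 21066 ± 1074 (SD, n = 3) in DMSO to 14697 ± 2451 at 48 h, a change of -30.2%, without overlap of the groups (exact p = 0.1, the smallest possible). FOXA1 peaks in 22Rv1 were at 74142 ± 14639 and 73109 ± 546 (n = 3, exact p = 1.0). This comparison was affected by depth: DMSO replicate 1 held 27342085 tags and 90541 peaks. DMSO replicates 2 and 3, with 14905023 and 14108348 tags, had 62391 and 69493 peaks. The treated libraries, with 13468989 to 15117077 tags, had 72478 to 73442. Whether the number of FOXA1 peaks changed can therefore not be told. The authors list 7584 of 23382 AR sites as lower and 1317 as higher. For FOXA1, 10003 of 88817 sites were lower and 10954 higher in 22Rv1, and 4350 of 71637 were lower and 5829 higher in MCF7. At FABP12 (chromosome 8) AR fell by 3.55 and FOXA1 by 3.05 on the log2 scale. AR also fell at LOC105378275 (-2.93) and MIR490 (-2.85) and rose at LINC02198 (2.73), LOC101927538 (2.13) and LOC105369911 (2.12). At the promoter of FKBP5, a classic AR target, the AR fold was -0.38 (FDR = 0.000439). FOXA1 fell at GCG (-3.15) and LOC105375377 (-2.79) and rose at OR6C64P (4.20), MIR3925 (5.46) and DLGAP1-AS2 (4.98). At MIR3925 and DLGAP1-AS2 the log2 concentrations in DMSO were only -0.13 and 0.28, so the sizes of these rises are uncertain. In MCF7 FOXA1 fell at LOC105376441 (-4.26), RNA5SP272 (-3.80) and GOT2P3 (-3.34) and rose at RPL27P3 (4.33), LOC100129667 (4.15) and LOC107986382 (4.01). Peaks in MCF7 were at 67688 ± 3300 in DMSO and 64840 ± 3945 at 48 h (n = 2, not tested).

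In the authors' table, H3K27ac was more often higher than lower near gene starts and more often lower than higher farther away. Within 1 kb of a gene start, 47.0% of 13972 sites were higher and 9.96% lower at 48 h. Farther away, 22.9% of 36032 were higher and 29.4% lower. Of all 50004 sites 14823 were higher and 11993 lower. H3K27ac over the promoter of NKX3-1 (chromosome 8, 23675069 to 23684266) had a fold of -2.66 (FDR = 5.83e-05), and the region of KLK3, which encodes prostate-specific antigen, one of -2.03 (FDR = 2.58e-62). At CDKN1A it rose by 2.35 (FDR = 4.89e-92). It also rose at MAX (1.23), MGA (1.07), ODC1 (1.01), MXD1 (0.99), MNT (0.83), NCL (0.40), CTCF (0.37) and CDK4 (0.27). It fell at FKBP5 (-0.72) and AR (-0.52), and the MYC promoter region had -0.05 (FDR = 0.738). Some named regions were at the table's lowest value in a condition, so no fold is given. RNU6-161P, RGS1 and BCHE went from log2 concentrations of 8.23, 8.16 and 7.99 to -0.18, and DLGAP1-AS2 and HKDC1 from -0.21 to 11.20 and 10.17. Peaks per library were at 36144 ± 1586 in DMSO and 35697 ± 26.9 at 48 h (n = 2, not tested). The share of tags in peaks was 53.3% ± 1.25 in DMSO, 59.2% ± 1.80 at 24 h and 67.1% ± 0.735 at 48 h.

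For ATAC in 22Rv1, 75548 of 226922 sites were less accessible and 46573 more accessible at 48 h in the authors' table. In MCF7 60176 of 221350 were less and 45384 more accessible. Near gene starts, 49.7% of the MCF7 sites were more and 14.7% less accessible, against 25.7% and 22.0% in 22Rv1. At CDKN1A accessibility rose at 2 promoter sites in both lines. The folds were 0.18 (FDR = 0.0404) in 22Rv1 and 0.38 in MCF7 at the site with the higher concentration, and 0.95 and 1.04 at the other. At KLK3 it fell by 1.01 in 22Rv1. The MYC promoter region had a fold of -0.64 (FDR = 4.86e-29) in 22Rv1 and 0.02 (FDR = 0.439) in MCF7. The largest falls by the rule were at LOC105378556 (-5.08), FAM3B (-4.37) and LOC100130331 (-4.36) in 22Rv1 and at MIR4495 (-3.32), LOC105376611 (-3.04) and MIR6779 (-2.70) in MCF7. The rises were at LOC100128007 (5.78), HECW1-IT1 (5.70) and MIR518D (5.59), and in MCF7 at KRT8P9 (3.68), NAA20P1 (3.46) and FUT1 (3.41). ATAC peaks were at 261758 ± 21758 and 268236 ± 29194 in 22Rv1 (n = 3, exact p = 0.8). In MCF7 they were at 281484 ± 29014 and 238728 ± 12069 (n = 3, exact p = 0.1, the smallest possible). The changes in the lines, 2.47% and -15.2%, differed by 17.7 points (permutation of treatment labels within each line, p = 0.12). That permutation assumes no change in either line, so whether they differ stays open.

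**Figure D4:**
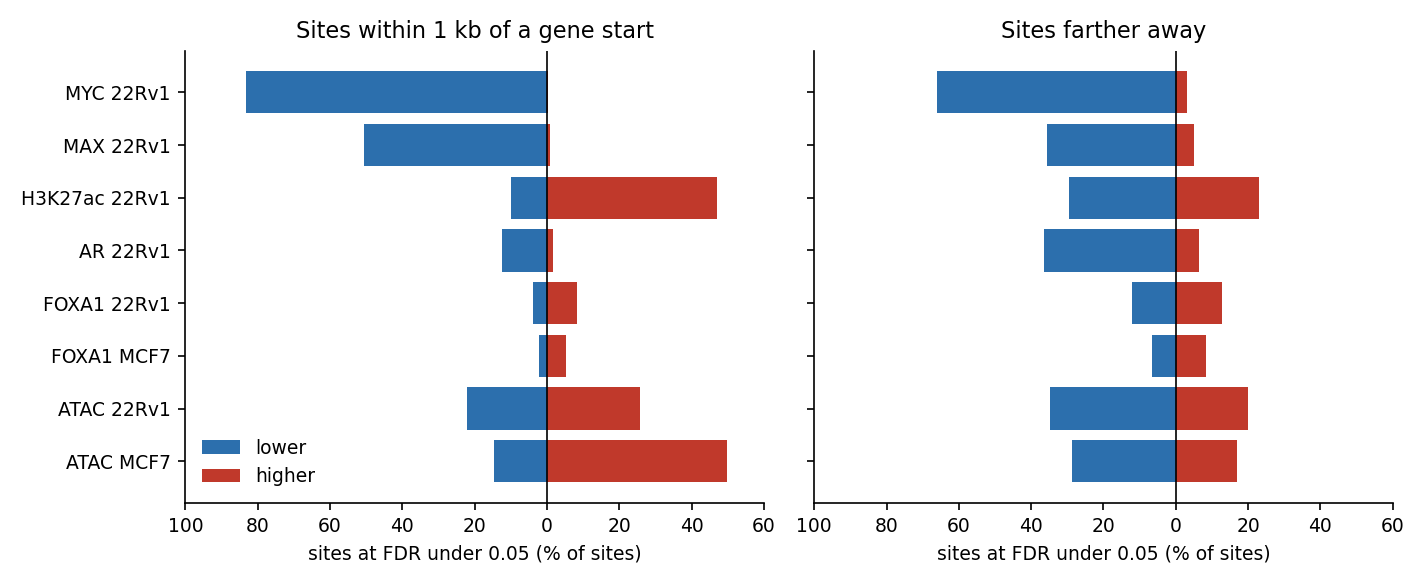
Share of the sites of each authors' table that were lower (left of 0) or higher (right of 0) at 48 h with FDR under 0.05, for sites within 1 kb of a gene start and farther away. For MYC 83.3% of sites near gene starts were lower, and for H3K27ac 47.0% of such sites were higher.

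CTCF peaks were at 63146 ± 2258 in DMSO and 63504 ± 135 at 24 h (n = 2). Among other MAX partners, MNT peaks went from 25735 ± 1078 to 20042 ± 812 and MGA peaks from 13893 ± 1369 to 11602 ± 667 at 48 h, without overlap of the groups (n = 2). MXD1 peaks were at 10722 ± 4399 and 11708 ± 802. Groups of 2 were not tested.

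Changes of the factors were compared site by site across the authors' tables. Of the sites with less AR, 60.1% overlapped a site with less FOXA1, against 7.60% of unchanged AR sites (odds ratio 18.3), and 89.3% overlapped a site with lower accessibility, against 47.0% (odds ratio 9.44). Of the sites with less MYC, 56.4% overlapped a site with less MAX, against 12.5% of unchanged MYC sites (odds ratio 9.02). The same sites overlapped a site with less H3K27ac in 20.6% of cases, against 11.9%, and a site with more H3K27ac in 28.6%, against 31.3% (odds ratio 0.875). Of the sites with less FOXA1, 85.5% overlapped a less accessible site in 22Rv1 and 75.9% in MCF7, against 30.2% and 16.96%. Of the sites with less H3K27ac, 83.3% overlapped a less accessible site, against 38.6%. Sites with more FOXA1 in 22Rv1 overlapped sites with more FOXA1 in MCF7 in 16.1% of cases, against 1.72% (odds ratio 10.9). Sites are not independent replicates, so these are descriptions.

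Promoter changes were set beside RNA changes at 48 h, across genes, which are not independent replicates. For H3K27ac, Pearson's r was 0.62 and Spearman's rho 0.57 over 12712 genes. At genes higher in RNA 75.2% of promoters had more H3K27ac, against 35.3% at genes lower in RNA. For MYC r was 0.39 and rho 0.32 over 12215 genes. Promoters had less MYC at 85.4% of genes higher in RNA and at 96.2% of genes lower in RNA. For MAX r was 0.32, for ATAC 0.32, for AR 0.16 and for FOXA1 0.09.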

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

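Of the tests in this part, the correlation of MYC and MAX folds and the test of H3K27ac sites above the lowest value were written down before their results were seen. The others were chosen after.

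In 4 of 86 groups of 4 libraries, a single library lay far from the other 3. Chance alone gives about 4.3 such groups (1 in 20). In the MAX ChIP at 4 h, replicate 2 had 9.13% of its tags in peaks, against 7.57% to 7.79% in the others. In the MYC ChIP at 1 h, replicate 4 had a peak at 85.1% of the consensus sites, against 91.5% to 92.1%. MYC RNA was at 104 CPM in replicate 1 at 48 h, against 86.1 to 86.8. WDR5 RNA was at 70.1 CPM in replicate 4 at 24 h, against 61.2 to 62.5.

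The effect of MYCi975 differed between 48 h and 24 h for 15 gene lists and 6 named genes, by a direct test of the 2 times. Median log2 differences were -1.87 for mitosis, -1.87 for replication-dependent histones and -1.12 for DNA replication and S phase. They were -0.68 for androgen receptor targets, -0.61 for neuroendocrine markers, -0.53 for glycolysis and hypoxia and -0.51 for nucleotide and one-carbon synthesis. Smaller differences were -0.29 for canonical MYC-activated genes, -0.22 for ribosome biogenesis, -0.22 for the prostate luminal lineage and -0.18 for cholesterol synthesis. Upward ones were 0.46 for p53 targets, 0.39 for endoplasmic reticulum chaperones, 0.31 for NRF2 genes and 0.15 for lysosome and autophagy. With an estimated correlation the calls for NRF2 genes (adjusted p = 0.0676), cholesterol synthesis (0.136), glycolysis (0.0992), lysosome (0.347) and the prostate luminal lineage (0.240) were lost. Among the named genes, log2 differences were -1.30 for MYC, 0.38 for MAX, 0.52 for MXD1, -0.39 for AR, -0.21 for FOXA1 and -0.18 for CTCF.

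The counts of changed genes were set against all 35 splits of the 8 libraries of a contrast. At 24 h, at 48 h and for 48 h against 24 h, 1 split, the real one, gave as many as 9556, 11007 and 7237 genes. The highest other split gave 0. The other splits mix the 2 groups, so the treatment effect adds to their spread, and their 0 is no measure of calls by chance. The real split would come first by chance in 1 of 35 cases. For the gap between MYC-bound and other genes, again 1 split of 35 was as large at 24 h (-0.20, highest other size 0.12) and 1 at 48 h (-0.20, highest other size 0.12). Mixing the groups shrinks any gap that goes with treatment. The splits therefore cannot tell whether bound genes differ beyond the correlation between genes. The camera test of that gave p = 0.00958 at 24 h and p = 0.0943 at 48 h with the preset correlation. For the number of gene lists, the splits can neither exclude chance nor measure it. As many lists came from 3 of 35 splits at 24 h (16 lists, highest other 17) and from 3 at 48 h (15 lists, highest other 15). The large counts came from splits with 3 libraries of a group and 1 of the other on a side, which keep part of the treatment effect (16 splits, median 13 lists at 24 h). The 18 splits with 2 of each group on a side gave at most 4 lists at 24 h and 3 at 48 h.

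MYC peaks were fewer at 48 h. Fewer sequenced tags do not explain it: the 3 libraries at 48 h with at least as many tags as the shallowest DMSO library (10875741) had at most 17141 peaks, against at least 30737 in DMSO. A uniform loss of ChIP yield at all sites stays open. MYC and MAX folds went together across 20865 shared sites (Spearman's rho 0.4835), but the test took this as evidence against such a loss wrongly, since sites with a shared background would give it too. Lower MYC RNA at 48 h may contribute.

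Sites with more MYC at 48 h numbered 964. More ChIP signal of any factor where chromatin opened may contribute: 94.8% overlapped a more accessible site, and the share with a CTCF peak rose by a ratio of 1.726, against 1.108 at sites with less MYC. The size of the rise varied by factor: from 5.86% to 10.1% for CTCF (libraries of 24 h), 2.80% to 13.2% for AR, 13.8% to 46.6% for FOXA1, 18.1% to 85.7% for H3K27ac and 8.12% to 57.2% for MAX. For MYC itself, by which these sites were chosen, the share went from 6.25% to 54.5%. CTCF rose least of these. In DMSO, 26.14% of the 964 sites were at the lowest value of the table (-0.40), so for those the size of the rise cannot be told. The median log2 concentration of the 964 in DMSO was 0.33, near that value. For many of the others the size is therefore uncertain too. Binding of MYC to newly opened sites stays open and was not tested apart from this.

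In the authors' table, H3K27ac was higher at promoters and lower farther away. A single scaling factor would move both alike, so it does not explain that the median log2 folds differed by 1.02. It does set where 0 lies, and the normalization is not stated. The opposite signs (medians 0.48 and -0.54) could therefore depend on it. Sites at the lowest value of the table do not explain the difference either. Above that value distant sites were still called lower more often, by 16.09 points, and 47.3% of promoter sites were called higher, against 19.0% of distant ones. The share of H3K27ac tags in peaks also rose, from 53.3% in DMSO to 67.1% at 48 h, and its part in the difference was not tested. A biological difference between promoter and distant sites stays a hypothesis from 2 libraries per condition.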

How the results depend on the processing

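Chosen after seeing the data were the fits without the 3 shallowest RNA libraries and those with the scaling factors of the authors' table. For the main counts and values, 128 of 140 alternative values were the same in direction, side of the threshold and, where untested, size; 10 moved in size and 2 came to pass. For named genes 3732 of 3741 were the same (8 lost their call, 1 reversed), for overlaps 167 of 168 (1 reversed) and for single lists 657 of 702 (34 lost their call, 9 came to pass, 2 reversed). For single peak comparisons 225 of 246 were labelled the same (12 moved in size, 5 came to pass, 4 reversed). There, paired differences were labelled the same by rule, and fits without a replicate were scored on size alone. Changes of sign in those fits were thus not counted as reversals.

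Leaving out single libraries gave 9092 to 9470 changed genes at 24 h, 10607 to 10908 at 48 h and 6476 to 7046 for 48 h against 24 h. The other alternatives gave 7987 to 9894, 9620 to 11999 and 5546 to 7288. With the replicate number as a replicate block the counts were 9349, 10890 and 6974. Lists changed numbered 13 to 17 at 24 h and 15 to 16 at 48 h without single libraries, and 15 and 20 with no filter on low counts. With an estimated correlation they were 7 and 8. The gap between MYC-bound and other genes ranged from -0.21 to -0.19 at 24 h and from -0.23 to -0.19 at 48 h without single libraries, and over the other alternatives from -0.22 to -0.12 and from -0.25 to -0.16. The value of -0.12 came from comparing within 10 bins of mean expression. At 48 h it passed with sites within 5 kb (-0.25, camera p = 0.0466) and with an estimated correlation (-0.20, p = 0.0225). The cause was not tested.

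These results reversed, and the cause was not tested. Peak comparisons without a replicate were not scored for a change of sign. AR RNA at 24 h was at 0.0529 in replicates 3 and 4 alone (adjusted p = 0.536). The mitochondrially encoded list at 48 h had a median of -0.10 without the 3 shallow libraries, and from -0.0313 (without DMSO replicate 2) to 0.164 (without DMSO replicate 1) without single libraries. MAX peaks at 1 h differed by 107 with a fold over input of at least 8 (exact p = 1.0), and MAX sites kept at 8 h by -0.833 points with consensus sites in all 4 DMSO libraries. With equal numbers of top peaks, sites kept passed in 6 of 10 comparisons, and MYC differed by 2.13 points at 4 h and 0.808 at 8 h. The odds ratio of less MYC with more H3K27ac was 1.02 at FDR under 0.01.

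Stricter thresholds lower counts by construction. At FDR under 0.01 the changed sites were 16417 for MAX, 13878 for FOXA1 in 22Rv1 and 6005 for FOXA1 in MCF7. With a 2-fold minimum they were 13734 for MAX, 63722 for ATAC in 22Rv1 and 39837 in MCF7. Centring left 22150 lower MYC sites. Spike-in scaling and motif counts were not run.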

Other observations

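The test of RNA at promoters with more MYC was written down before its result was seen; the others in this part, and the genes named here, were chosen after.

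At sites with less MYC at 48 h, the share with a peak went from 76.0% to 57.3% for MAX, as means of 4 libraries. For MNT it went from 60.2% to 47.6%, for MGA from 33.6% to 26.2% and for MXD1 from 27.0% to 28.3%, as means of 2. The MXD1 libraries in DMSO were at 19.6% and 34.4%, on either side of the treated ones (29.5% and 27.0%). The direction for MXD1 can therefore not be told. At sites where the authors list MYC as not changed, the share also went down for MAX, from 43.6% to 35.0%, for MNT, from 24.6% to 21.0%, and for MYC itself, from 34.9% to 16.3%. At sites with more MYC the share rose for each of these factors: MAX from 8.12% to 57.2%, MNT from 4.56% to 21.7%, MGA from 1.56% to 20.4% and MXD1 from 1.25% to 10.2%. FOXA1 there went from 13.8% to 46.6% and H3K27ac from 18.1% to 85.7%.

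Genes that gained MYC at their promoter may be more active at 48 h. Of 43 tested genes with such a promoter, 37 were higher in RNA and 3 lower, so that 92.5% of the changed ones were higher, against 50.19% of all other changed genes. Among them were CALCA (6.04), CLGN (2.58) and ATF6 (1.68). As chromatin opened at most sites with more MYC, the gain of MYC is not shown to be the cause.

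A deposited table of MYC-bound genes carries normalized counts under a name that speaks of a spike-in. All 8 of its library factors were within 0.1% of median-of-ratios factors of the gene counts, so a separate scaling by a spike-in is not seen in these values.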
